A study of Mus musculus with 10 samples.

How the data were processed

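Laser-dissected colon tumours of KO and WT mice were profiled on Affymetrix Mouse Genome 430 2.0 arrays, 1 array per tumour. Per the labels, mice aged 6 to 8 weeks received dimethylhydrazine at 44 mg/kg and then 2% dextran sulfate sodium for 7 days, colon segments of 1 cm were cut into sections of 14 µm, RNA was taken up in 20 µL and 30 ng were amplified. The extraction text speaks of pooling samples of a mouse, whereas several arrays are listed for single mice, and the titles call tumour what the design text calls a unique number. The arrays were treated as single tumours, as listed. The deposited values are log2 signals per probe set, made by the authors with RMA (background correction, quantile normalisation and summary per probe set, version not given). Their distributions were nearly equal across the 10 arrays. The number of arrays limits the precision, and signal over background was not analysed here for single genes.

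Of 45101 probe sets, 64 were Affymetrix controls, 34945 had 1 gene symbol, 932 had several and 9160 had none. Symbols were matched by Entrez identifier for 34741 probe sets, and 204 kept the name in the annotation. Gene names and gene order came from the mouse assembly GRCm38.p6, no build being named by the study. For each of 18193 genes the probe set with the highest mean was taken, and 12250 genes were tested, those with a mean at or above the 40th percentile of all probe sets (log2 5.82). KO was compared with WT by limma 3.58.1 (lmFit and eBayes, R 4.3.3, statmod 1.5.0) with the mouse as a random block. The consensus correlation of tumours of a mouse was 0.0586. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05.

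The gene lists, 23 in number, the rule for naming genes and the alternatives were fixed before the data were examined. Lists with at least 5 tested members, 21 of them, were tested with cameraPR at a preset correlation of 0.01, with camera at an estimated correlation, and with fry and the mouse block. With the preset correlation 6 lists passed, and with an estimated correlation 0 lists passed. The enteroendocrine list had 4 tested members and the sex-linked list was left out of the test. Named genes were Bcl9 and Bcl9l, the 10 largest rises and 10 largest falls past the threshold without overlap of KO and WT arrays (clone names, immunoglobulin and T cell receptor segments left out), and for each list the 2 to 4 members with the smallest p. Other members of the lists were named with their values. Array measures, 6 in all, were compared by exact two-sided permutation tests.

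The fit was tested on simulated data with 200 changed genes. At a simulated correlation of 0.0586 between tumours of a mouse, the fit with the mouse block recovered 71% of 2-fold and 95% of 4-fold changes, with 5.14% false calls, and mouse means recovered 21% and 79%. At a correlation of 0.3 the block fit recovered 68% and 94%, with 5.81% false calls, and mouse means 7% and 70%. Without an effect it made 0 calls in either fit. In a list test with 1 lowered list, 0 of the 17 lists that share no member with it passed. Genes were simulated as independent of each other, so this result cannot check the preset correlation of 0.01. In the real data the estimated correlation was 0.197 for Wnt targets and 0.887 for MHC class II genes.

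The alternatives were no block, mouse means, the range of unique sample numbers as a covariate, each range alone, no level filter, a filter at the 60th percentile, the mean of all probe sets per gene, no probe sets ending in x_at or s_at, arrays centred on the median, cyclic loess, eBayes with trend and robust, array weights, the 3′ to 5′ difference as a covariate, each tumour and each mouse left out, and a fold of at least 2. The range covariate for the targeted probe sets and 5 further gene lists were added after the data were seen. Probe sets without a single gene name were left out of the gene comparison.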

Results

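Gene expression was measured in laser-dissected colon tumours of mice given dimethylhydrazine, a carcinogen precursor, and then dextran sulfate sodium, which injures the colon. The tumours came from wild-type mice (WT) and from mice carrying vil-Cre and lacking Bcl9 and Bcl9l (KO), both of a mixed strain background. In which cells of the dissected tissue the genes were lost was not examined here. Bcl9 and Bcl9l are co-factors that link beta-catenin to Pygo proteins in Wnt-driven transcription. Each tumour was hybridised to 1 Affymetrix mouse array, giving 5 KO tumours from 3 mice and 5 WT tumours from 2 mice. Of the WT tumours, 4 came from mouse 72 and 1 from mouse 82. Of the KO tumours, 2 came from mouse 02, 2 from mouse 04 and 1 from mouse 99. The deposited values are log2 RMA signals for 45101 probe sets per array, whose medians ranged from 6.43 to 6.50. The number of arrays and mice limits the precision, and no detection calls were used here, so no statement is made on which genes lay above background.

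The probe sets of the targeted genes were compared first, to ask whether the arrays themselves show the deletion. None of the 5 probe sets was lower in KO tumours past the threshold of the limma test, and 1, a probe set of Bcl9, had an unadjusted p under 0.05, with the higher mean in KO. For Bcl9, probe set 1451574_at was at 8.49 ± 0.20 log2 in KO and 8.28 ± 0.22 in WT tumours (SD, n = 5 tumours each), and probe set 1455565_at was at 7.36 ± 0.22 and 7.05 ± 0.20. For Bcl9l, probe set 1419180_at was at 8.40 ± 0.22 in KO and 8.27 ± 0.15 in WT, probe set 1438806_at at 7.08 ± 0.30 and 6.91 ± 0.18, and probe set 1443700_at at 4.62 ± 0.05 and 4.76 ± 0.05. The last of these lay below the level filter used for other genes, and its 5 KO tumours were all lower than its 5 WT tumours, by 0.14 log2 on average (difference −0.14 ± 0.08, SE, adjusted p = 0.248). The adjusted p-values over the 5 probe sets ranged from 0.222 to 0.346 (limma, mouse as a random block). Where these probe sets lie relative to the deleted part is not stated in the labels, so they check nothing about the genotypes, and the tumours are called KO and WT below because they are labelled so.

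**Figure D1:**
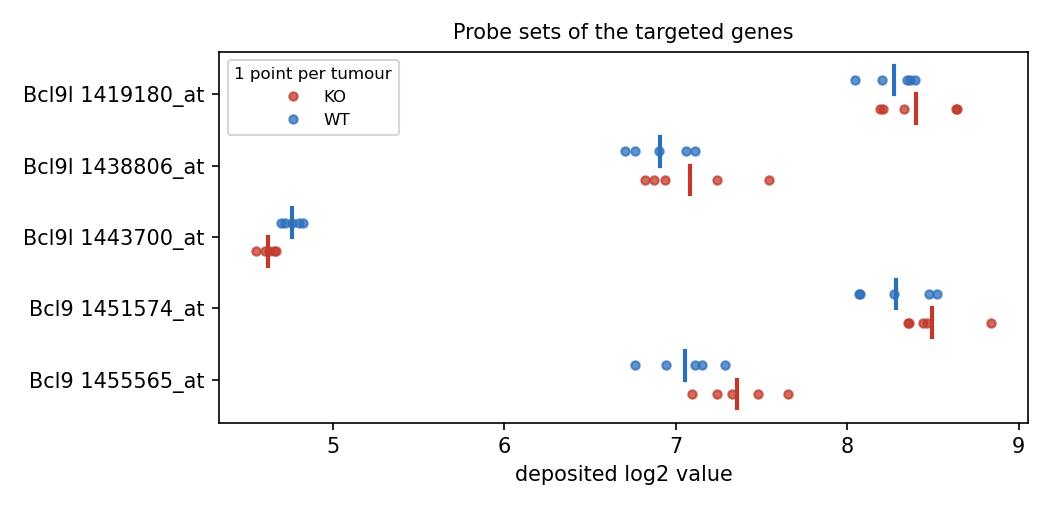
Deposited log2 values of the 5 probe sets of Bcl9 and Bcl9l, with 1 point per tumour (KO red, WT blue) and a bar at each group mean. KO means of Bcl9 lie above the WT means, 8.49 against 8.28 and 7.36 against 7.05, with overlapping tumours, whereas the tumours of Bcl9l probe set 1443700_at do not overlap (4.62 against 4.76).

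The comparison of KO with WT tumours asks which genes depend on Bcl9 and Bcl9l in these tumours. Among the genes that fell in KO tumours were Pnliprp1 and Pnliprp2, related to pancreatic lipase, at 53.2-fold and 44.4-fold lower levels (4.80 ± 0.66 against 10.56 ± 1.44 and 6.47 ± 0.67 against 11.96 ± 0.84 log2, SD, n = 5 tumours each). The proteoglycan gene Spock2 was 43.0-fold lower, the growth factor gene Ptn 36.4-fold, the pyruvate dehydrogenase kinase gene Pdk4 34.5-fold and Bex1 30.5-fold. The matricellular gene Thbs2 was 19.1-fold lower and Nptx1 14.2-fold, and the Wnt antagonists Dkk2 and Apcdd1 were 22.1-fold and 18.7-fold lower. Among the genes that rose were the chemokine gene Cxcl9, at a 32.6-fold higher level (9.85 ± 0.82 against 4.79 ± 1.08), and Ido1, which encodes a tryptophan-degrading enzyme, at 31.5-fold (10.71 ± 1.69 against 5.70 ± 1.35). The guanylate-binding protein genes Gbp2b and Gbp2 were 23.9-fold and 19.3-fold higher and Gbp3 was higher by 3.90 log2, the ubiquitin-like gene Ubd 18.2-fold and the interferon-inducible GTPase gene Iigp1 16.1-fold. Nlrc5, a transactivator of MHC class I genes, was 15.1-fold higher, the class I gene H2-Q5 13.4-fold and complement C2 12.2-fold. These 20 genes had adjusted p-values from 0.000207 to 0.0135 (limma, Benjamini-Hochberg) and no overlap between KO and WT tumours. Over mouse means Gbp2, Ido1, Iigp1, Ptn and Ubd did not pass (adjusted p = 0.0671, 0.0553, 0.0549, 0.0970 and 0.104), and Ptn did not pass without mouse 02. Among tumours with unique sample numbers 254 to 258, Bex1, Dkk2, Ido1, Ptn and Ubd did not pass, and among those numbered 191 to 229 Cxcl9, Dkk2, Gbp2, Gbp2b, Gbp3, Ido1, Iigp1, Nlrc5, Nptx1, Pdk4, Pnliprp1, Thbs2 and Ubd did not. Without mouse 72, which gave 4 of the 5 WT tumours, Bex1, C2, Dkk2, Gbp2, Gbp2b, Ido1, Iigp1, Ptn, Spock2 and Ubd did not pass. Pnliprp1, Pdk4, Thbs2 and Nptx1 in KO tumours, and Cxcl9, Ido1 and H2-Q5 in WT tumours, had means under the level filter of 5.82 log2, where background was not assessed, so their folds, by which they were chosen, are not exact. Genes of the Gbp, H2-Q and Pnliprp families have near copies that a probe set cannot always tell apart.

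Of 12250 genes tested, 868 changed, 509 higher and 359 lower in KO tumours (limma, adjusted over all genes tested), and the median difference over all genes was 0.03 log2. In 747 of the 868, the 5 KO tumours did not overlap the 5 WT tumours. Among all genes tested such a separation occurred in 9.12%, where chance gives 0.794% if the 10 tumours are taken as independent, and differences between mice would raise that share. With 1 mean per mouse, which leaves 3 KO against 2 WT mice, 195 genes were higher and 193 lower, of which 315 were among the 868. All 868 kept their sign, which is no separate support, since mouse means average the same tumours. For the 747 genes without overlap the sign was fixed in advance. The counts were 135 higher and 153 lower without mouse 72, 265 and 202 without mouse 04, 318 and 230 without mouse 02, 286 and 186 without KO tumour 6, 318 and 219 without WT tumour 1, and 331 and 217 with the 3′ to 5′ difference of control probe sets as a covariate. Unique sample numbers fall into the ranges 191 to 229 (1 KO, 4 WT) and 254 to 258 (4 KO, 1 WT). Within the lower range 12 genes were higher and 18 lower, within the upper range 412 and 326, and with the range as a covariate 390 and 424. The range-only fits, and the fit without mouse 72, leave 1 tumour in a group. They assume that it varies like the others, so their counts, calls and p-values, given above and below, are not reliable. The mean correlation with the other arrays spread more among WT (SD 0.0045) than among KO tumours (SD 0.0011). WT tumour 1, the lone WT tumour of the upper range, had the lowest such correlation (0.964, other arrays 0.970 to 0.976).

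Because Bcl9 and Bcl9l act in Wnt transcription, a list of Wnt target genes was compared first. Of 28 members tested, 13 fell, 2 rose and 13 did not pass (adjusted over the list alone, 14 fell and 5 rose). Each KO tumour had a lower mean over the list than each WT tumour. Apcdd1 and Dkk2 are given above, and the secreted inhibitor gene Wif1 fell by 3.76 ± 0.63 log2 (SE), a 13.5-fold change. The homeobox gene Prox1 was 9.38-fold lower (8.41 ± 0.79 against 11.62 ± 0.53, SD, n = 5 tumours each) and the feedback inhibitor Nkd1 9.02-fold. Lef1, a partner of beta-catenin on DNA, was 5.83-fold lower and the stem cell receptor gene Lgr5 5.81-fold lower (5.41 ± 0.83 against 7.96 ± 0.34). Axin2, a widely used readout of Wnt activity, was 1.96-fold lower (11.38 ± 0.29 against 12.34 ± 0.33), with an adjusted p of 0.0158 over tumours and 0.0757 over mouse means (limma). The other members that fell were Tnfrsf19, Sp5, Notum, Znrf3 and Etv4, with differences of −3.14, −2.86, −1.50, −1.37 and −0.88 log2. The KO mean of Lgr5 lay under the level filter, so its fold is not exact. Over mouse means Wif1, Tnfrsf19, Notum, Etv4, Mmp7 and Myc did not pass (adjusted p = 0.0653, 0.0708, 0.0772, 0.372, 0.0823 and 0.0671), and with the number range as a covariate Etv4 and Mmp7 did not (0.135 and 0.0757). Mmp7, a matrix metalloproteinase, and Myc went the other way, with 1.90-fold and 1.69-fold higher levels. Cd44, Ccnd1, Sox9 and Ascl2, which did not pass, had differences of 0.58, 0.14, 0.18 and 0.38 log2. The list as a whole was lower than other genes, with a mean difference of −1.13 and a median of −0.46 log2 (cameraPR, adjusted p = 1.83e-09 with a preset correlation; adjusted p = 0.444 with an estimated correlation). The mean difference was −1.27 within the lower number range and −1.41 within the upper range.

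**Figure D2:**
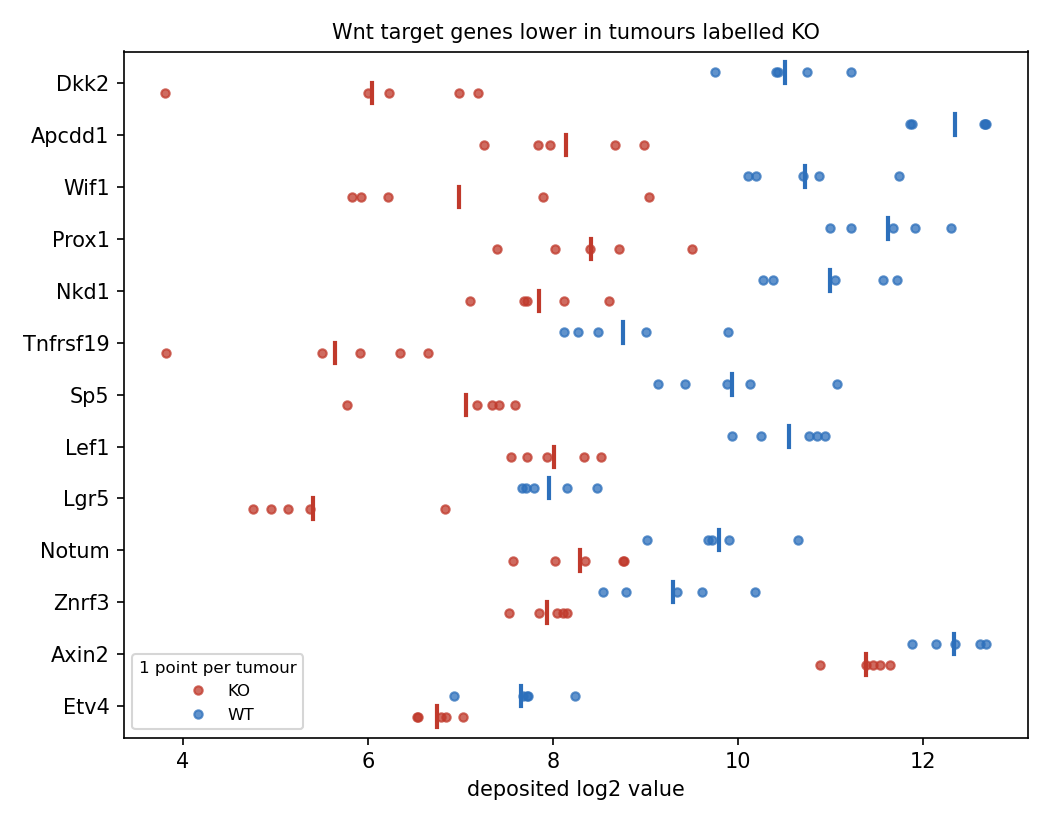
Deposited log2 values of the 13 Wnt target genes that fell, with 1 point per tumour (KO red, WT blue) and a bar at each group mean. Lgr5 lies at 5.41 on average in KO and 7.96 in WT tumours, and Axin2 at 11.38 and 12.34.

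Intestinal stem cell markers moved apart. Of 20 tested, 6 fell and 1 rose (adjusted over the list alone, 8 and 7). Smoc2 was 7.93-fold lower (7.28 ± 0.85 against 10.26 ± 0.62, SD, n = 5 tumours each) and the RNA-binding protein gene Msi1 3.78-fold lower, beside Lgr5, Tnfrsf19, Axin2 and Znrf3, which the Wnt list also holds. The rise was in Lrig1, an inhibitor of growth factor receptors, by 1.94-fold. The list has 9 tested members in common with the Wnt list, and its mean difference was −0.49 log2, which did not pass (cameraPR, adjusted p = 0.127; adjusted p = 0.791 with an estimated correlation). It was −0.62 within the lower number range, with 1 KO tumour, and −0.66 within the upper, with 1 WT tumour. The list passed with the range as a covariate (−0.64, adjusted p = 0.00713), without KO tumour 2 (−0.58, adjusted p = 0.0149) and without mouse 02 (−0.63, adjusted p = 0.00752). Msi1 and Lrig1 did not pass over mouse means (adjusted p = 0.163 and 0.0917). Genes of the Wnt transcription complex itself differed little, with a mean difference of −0.17 log2 over 13 members (adjusted p = 0.211). The only member to pass was Lef1. Ctnnb1, which encodes beta-catenin, had a difference of −0.20 log2 (adjusted p = 0.210).

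A list of mesenchymal and epithelial-to-mesenchymal transition genes was compared between KO and WT tumours. The arrays measure dissected tissue, so this programme cannot be assigned to tumour cells. Of 22 members, 2 fell and none rose past the threshold (adjusted over the list alone, 5 fell). Vim, which encodes the intermediate filament vimentin, was 2.32-fold lower (11.58 ± 0.31 against 12.79 ± 0.29, SD, n = 5 tumours each) and Fn1, fibronectin, was 2.81-fold lower (9.79 ± 0.46 against 11.30 ± 0.61). Zeb1 and Snai2, transcription factors of the programme, had differences of −0.13 and −0.24 log2 and did not pass. The list mean was −0.42 log2 (cameraPR, adjusted p = 0.00222; adjusted p = 0.781 with an estimated correlation), −0.39 within the lower number range, −0.56 within the upper, where it no longer passed (adjusted p = 0.0553), and −0.25 without mouse 04, where it did not pass either (adjusted p = 0.0877). With the 3′ to 5′ difference of control probe sets as a covariate it was −0.25 (adjusted p = 0.0432). Fn1 did not pass over mouse means (adjusted p = 0.175). Fibroblast markers, of which 3 are also in the mesenchymal list, were lower in the same tumours as a group, by a mean of −0.50 log2 (cameraPR, adjusted p = 0.0283; adjusted p = 0.781 with an estimated correlation). None of 14 passed alone and 3 had an unadjusted p under 0.05. The mean was −0.69 without WT tumour 3, whose list mean of 9.06 stood apart from the other WT tumours (10.02 to 10.15). The fibroblast call was lost without KO tumour 7, 9 or 11 and without WT tumour 1, 8, 12 or 13, with adjusted p-values up to 0.0877, and without mouse 04 (−0.35, adjusted p = 0.161). It was also lost within the lower and upper number ranges (−0.61 and −0.64, adjusted p = 0.0630 and 0.0656) and with the 3′ to 5′ difference as a covariate (−0.31, adjusted p = 0.150). Epithelial junction and keratin genes, 20 in all, had none past the threshold and a mean difference of 0.00 log2, with 4 at an unadjusted p under 0.05. Cdh1, E-cadherin, had a difference of 0.34 log2 (adjusted p = 0.189).

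Lymphocyte genes were higher in KO tumours. Of 11 tested, 8 rose (10 adjusted over the list alone). The T cell gene Cd8a was 6.51-fold higher (8.48 ± 0.42 against 5.77 ± 0.27, SD, n = 5 tumours each), the chemokine gene Ccl5 7.82-fold, and the B-lineage genes Jchain and Cd79a 6.71-fold and 3.52-fold. The WT means of Cd8a, Ccl5 and Cd79a lay under the level filter, so these folds are not exact. Cd4 had a difference of 0.05 log2. Each KO tumour had a higher mean over the list than each WT tumour. The list mean difference was 1.70 log2 (cameraPR, adjusted p = 3.66e-18; adjusted p = 0.192 with an estimated correlation), 1.92 within the lower and 1.75 within the upper number range. Of myeloid markers, only Cd14 rose among 15 tested (2 adjusted over the list alone), by 3.76-fold, and the list mean difference was 0.23 log2 (adjusted p = 0.288), and 0.01 without WT tumour 3.

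Genes of antigen presentation and of the interferon response were higher in the same tumours. All 6 MHC class II genes tested rose, the transactivator gene Ciita by 6.24-fold (8.33 ± 0.66 against 5.69 ± 0.26, SD, n = 5 tumours each), H2-DMa by 7.61-fold, the invariant chain gene Cd74 by 5.19-fold and H2-Eb1 by 4.85-fold. Their mean difference was 2.37 log2 (cameraPR, adjusted p = 4.22e-17; adjusted p = 0.255 with an estimated correlation), 2.80 within the lower and 2.01 within the upper number range. H2-Aa did not pass with the range as a covariate (adjusted p = 0.0517). Of 12 interferon response genes, 6 rose (9 adjusted over the list alone). They were Cxcl9 and Gbp2, given above, Cxcl10 at 11.4-fold (9.23 ± 1.24 against 5.71 ± 0.68), Oasl2 at 5.64-fold, Ifit2 at 6.44-fold and Oas1a at 2.53-fold. The WT means of Ciita, Cxcl10 and Nos2 lay under the level filter, so their folds are not exact. Usp18 and Irf7 did not pass, at −0.10 and 0.96 log2. The mean difference of the list was 2.25 log2 (adjusted p = 5.00e-09; adjusted p = 0.444 with an estimated correlation), 2.93 and 2.42 within the lower and upper number ranges. It was 1.75 without mouse 04 and 2.99 without mouse 02, whose tumours 2 and 6 had list means of 8.13 and 7.70 against 9.68 to 9.86 in the other KO tumours and up to 7.66 in WT tumours. Lymphocyte genes, given above, were higher in the same KO tumours, by 1.70 log2. Besides Gbp2, Ifit2 (adjusted p = 0.0782), Oas1a (0.0601) and Cxcl10 (0.0727) did not pass over mouse means (limma). Of 15 inflammation genes, only Nos2 rose, over all genes and adjusted over the list alone, by 3.69-fold (limma, adjusted p = 0.0445 over tumours, 0.188 over mouse means). The list mean difference was 0.12 log2 (cameraPR, adjusted p = 0.936), 0.39 without KO tumour 6 and −0.14 without WT tumour 3. Il1b, Cxcl1 and Saa3 had differences of 1.21, 0.24 and −1.39 log2 that did not pass.

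**Figure D3:**
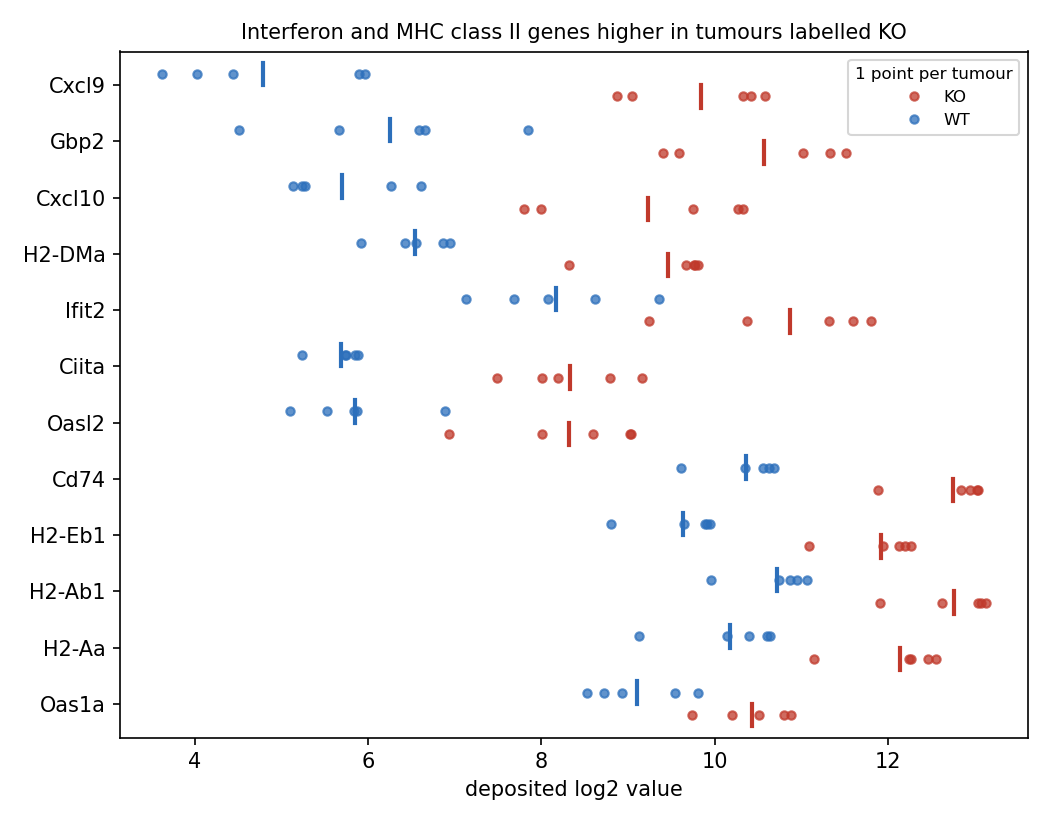
Deposited log2 values of the 12 interferon response and MHC class II genes that rose, with 1 point per tumour (KO red, WT blue) and a bar at each group mean. Cxcl9 lies at 9.85 on average in KO and 4.79 in WT tumours, and Cd74 at 12.75 and 10.37.

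Lists for other cell types and processes were compared to see what else differed between the tumours. Of the 21 lists, 10 had no member past the threshold, over all genes or over the list alone. Among 21 proliferation genes none had an unadjusted p under 0.05, and the list mean difference was 0.09 log2 (adjusted p = 0.932). Of 12 goblet cell genes, 3 had an unadjusted p under 0.05. Spink4, Agr2 and Atoh1 were higher by 2.40, 1.31 and 1.26 log2 without passing, and the list mean was 0.71 (adjusted p = 0.176), 0.27 without WT tumour 1, and 0.99 without WT tumour 3, where it passed (adjusted p = 0.0358). Over mouse means Spink4, Muc2, Tff3 and Atoh1 passed (adjusted p = 0.0150, 0.0294, 0.0322 and 0.0395). Guca2b, a gut peptide gene, rose 1.81-fold as the only change among 12 absorptive colonocyte genes (adjusted over the list alone, 1 rose and 1 fell), whose median was 0.19, mean −0.07 log2 and test direction upward (adjusted p = 0.936). Guca2b did not pass over mouse means (adjusted p = 0.0784), with the 3′ to 5′ covariate, within either number range, without KO tumour 6 or 7, without WT tumour 1, 8 or 13, or without mouse 02, 72, 82 or 99. Of 10 Paneth and antimicrobial genes, Mmp7 and Nos2 rose (adjusted over the list alone, 4 rose and 1 fell; mean 0.59 log2, adjusted p = 0.252). Smooth muscle, endothelial, cholesterol synthesis, immediate early and heat shock, and distal HOX genes had mean differences of −0.16, −0.37, 0.16, 0.29 and −0.35 log2, with adjusted p-values from 0.176 to 0.932. Unadjusted p-values under 0.05 were reached by 1, 2, 0, 3 and 1 of their members. Some of these means depended on single tumours. The distal HOX mean was −0.69 without KO tumour 6 and −0.16 without KO tumour 9, and 0.02 without mouse 04. The smooth muscle mean was −0.29 without WT tumour 3 and −0.07 without KO tumour 9. Glycolysis and hypoxia genes had a mean difference of 0.03 and a median of 0.05 log2, against a test direction downward (adjusted p = 0.936), with 1 member at an unadjusted p under 0.05. Several of these lists passed with samples left out. Endothelial genes passed without KO tumour 2 (cameraPR, adjusted p = 0.0291), WT tumour 3 (0.0169) and mouse 02 (0.0235). Without mouse 02, Paneth (0.0153), inflammation (0.0153), smooth muscle (0.0366) and immediate early genes (0.0366) passed. Leaving out mouse 72 leaves 1 WT tumour, so the spread among WT tumours is not measured there. Endothelial, goblet, Paneth, proliferation and cholesterol genes then had mean differences of −0.77, 0.82, 1.16, 0.60 and 0.52 log2. The 4 enteroendocrine genes tested, too few for a list test, included Chga and Chgb at 1.26 and 2.43 log2 (adjusted p = 0.160 and 0.171).

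**Figure D4:**
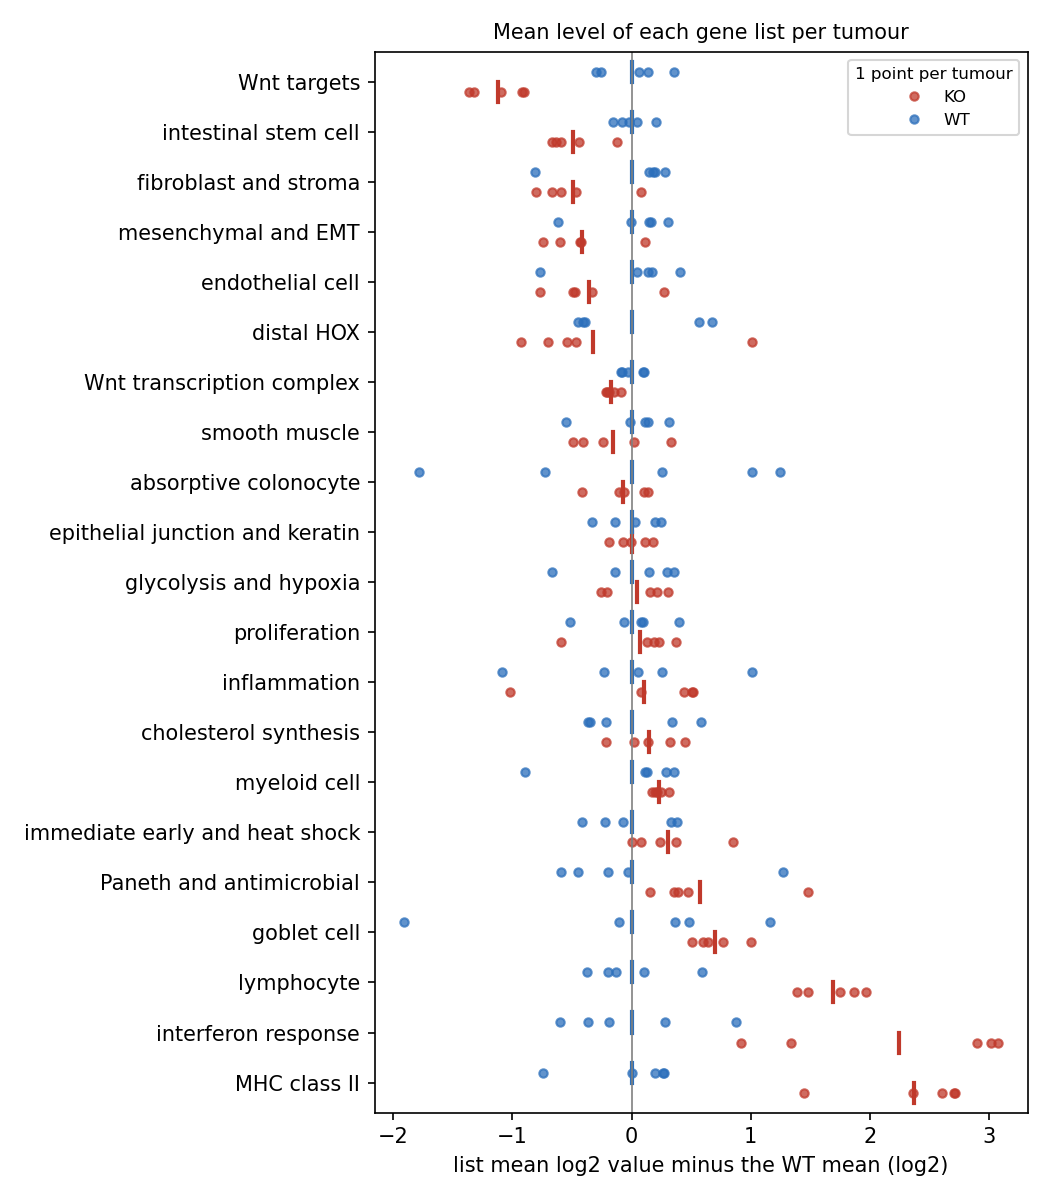
Mean log2 value of each gene list per tumour minus the WT mean of that list, with 1 point per tumour (KO red, WT blue) and a bar at each group mean. The KO means lie from −1.12 for Wnt targets to 2.37 for MHC class II genes.

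The arrays separated by genotype on the first principal component, which held 44.2% of the variance (exact permutation test over tumours, two-sided p = 0.00794, adjusted p = 0.0476 over 6 array measures). The difference between 3′ and 5′ control probe sets for Gapdh and beta-actin, a sign of RNA quality, averaged 0.86 ± 0.19 in KO and 0.96 ± 0.13 log2 in WT tumours (exact permutation p = 0.381, adjusted p = 0.457). Over mouse means, 3 against 2 animals, an exact test cannot go below 0.1. All arrays had high Xist and low Y-linked signals.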

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

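The tests of number ranges, of the share of epithelium or stroma, of lymphocytes as a source, of the H2 genes, of swapped tumours and of the position of the targeted probe sets were chosen after the result was seen.

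The tumours were split into other groups of 5 to ask whether chance gives results as large, with 100 splits drawn, the real one included. These splits take tumours as independent, although of those drawn the real split alone keeps each mouse whole, so they do not exclude chance among mice. Over tumours so taken, the real split called 876 genes in the form used for splits, and other splits at most 119 (1 split as large). The real split was also the largest for Wnt targets (minus log10 p 9.58, highest other 4.44), lymphocyte (18.8 and 10.5) and MHC class II genes (17.4 and 12.3), each with 1 split as large. Other splits leave the KO to WT difference in the spread within their groups, which can lower their counts. With tumours nested in 5 mice, these results do not exclude chance. Chance cannot be excluded either for interferon genes (9.01, highest other 16.0, 6 splits as large), mesenchymal genes (3.28 and 17.7, 29 splits) or fibroblast genes (2.09 and 20.8, 42 splits). The 5 mice allow 10 splits, too few for a share under 0.05, and the real one gave 388 genes against 0 in any other. The gene lists were not tested by splits of mice.

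Interferon and MHC class II genes that rose were higher in KO tumours by 2.80 log2 on average (12 genes, 95% confidence interval 1.97 to 3.63 over tumours). They were picked because they rose in these same tumours. All 18 tested members, called or not, were higher by 2.29 (1.33 to 3.25). With the number range as a covariate the difference was 3.04 (1.96 to 4.12), and 2.58 (1.34 to 3.83) for all 18 tested members, called or not. It rests largely on KO tumour 7 and WT tumour 1, each alone of its genotype in its range. Mice were not modelled, so a shift between ranges is not excluded as the whole cause. Lymphocyte minus stromal genes differed by 2.04 (1.24 to 2.84), with stromal genes alone at −0.35 (−0.89 to 0.20). These values argue only against a rise of lymphocytes and stroma together. A lower share of epithelium beside more lymphocytes cannot be told apart, since lymphocyte and stromal genes need not move alike. Strain variants in the members' own genes were looked at only close beside Bcl9 or Bcl9l and at the H2 genes. Within 200 gene places of Bcl9 or Bcl9l lie 0 of the 12 members that rose. Of 11751 tested genes only 419 lie there, so 0 was a likely count in advance, and linked variants farther away are not addressed. The 13 members away from the H2 genes were higher by 2.37 (1.26 to 3.49; over mouse means 2.39, 0.04 to 4.75). This argues against own-gene variants at the H2 genes as the whole cause, with a mouse-mean interval that nearly reaches 0. It cannot speak on variants in the H2 members themselves, which it leaves out. More lymphocytes as the whole source cannot be told apart. The difference beyond lymphocyte genes was 1.11 (0.35 to 1.87) for the 12 genes that rose. It was 0.60 (−0.28 to 1.48) for all 18 tested members and 0.94 (−0.48 to 2.36) over mouse means. The genotype and strain variants in the H2 members, elsewhere or in a linked regulator of distant genes stay open. So do a shift between number ranges and the mice themselves, with 3 KO and 2 WT mice.

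Wnt target genes that fell were lower by a mean of −2.66 log2 (13 genes, −3.26 to −2.06). They were picked because they fell in these same tumours, so this interval is no test of the fall. With the number range as a covariate the difference was −3.05 (−3.63 to −2.47). This rests largely on KO tumour 7 and WT tumour 1, each alone of its genotype in its range. They had the lowest and highest scores of all tumours (7.10 and 10.80), so a shift between ranges is not excluded. With the 3′ to 5′ difference as a covariate it was −2.61 (−3.28 to −1.93), which argues, over tumours, against RNA quality as the whole cause. Mice were not modelled in either interval. Relative to fibroblast genes the difference was −2.17 (−2.82 to −1.51; over mouse means −3.36 to −0.98). Over all 28 tested members, called or not, the difference was −1.12 (−1.48 to −0.76). There these 3 differences were −1.35 (−1.71 to −0.98), −1.06 (−1.44 to −0.68) and −0.63 (−1.11 to −0.15). The last argues, over tumours, against a lower share of stroma as the whole cause only if Wnt target and fibroblast genes move alike with stroma. That was not shown, and the fall was smaller relative to fibroblast genes. No interval over mouse means was taken for this difference of all members. Loss of Bcl9 and Bcl9l may account for the falls, a hypothesis that no test here decides, and a difference between the few mice stays open.

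No probe set of Bcl9 or Bcl9l was lower in KO past the threshold (0 of 5). Single tumours swapped between the groups are argued against by 0 arrays correlating better with the other group, while an exchange of all labels is not excluded. Probe sets outside the deleted part cannot be told apart from other explanations, since the labels do not give that part. No biological explanation was tested.

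Of 266 groups of values, 26 held a tumour far from the others of its group, where chance gives 13.3. Members of a list and its mean are counted separately though they move together, so these counts do not show an excess. KO tumour 2 stood apart with Pdk4 at 4.38 (others 4.02 to 4.10), Nptx1 at 4.54 (5.0 to 5.19), H2-DMa at 8.32 (9.67 to 9.81), Cd74 at 11.89 (12.84 to 13.04) and H2-Eb1 at 11.08 (11.95 to 12.27). Its list means were 10.31 for MHC class II (11.22 to 11.58) and 10.05 for Paneth and antimicrobial genes (8.72 to 9.04). WT tumour 3 had Fcer1g at 6.61 (7.21 to 7.36), Myl9 at 8.72 (9.67 to 10.05), Ciita at 5.24 (5.74 to 5.89) and H2-Eb1 at 8.80 (9.65 to 9.95). Its list means were 8.09 for myeloid (9.10 to 9.34), 9.06 for fibroblast (10.02 to 10.15) and 8.11 for MHC class II genes (8.86 to 9.13). KO tumour 6 had Chga at 10.05 (7.68 to 8.29), Lcn2 at 3.95 (7.11 to 8.07) and Hoxd13 at 11.38 (3.63 to 4.45), with list means of 7.17 for inflammation (8.27 to 8.70) and 9.50 for distal HOX genes (7.56 to 8.02). KO tumour 9 had Aurkb at 7.21 (8.05 to 8.36), Lyz2 at 11.85 (12.14 to 12.25), Bcl9 probe set 1451574_at at 8.84 (8.35 to 8.47) and a proliferation list mean of 8.80 (9.52 to 9.76). WT tumour 1 had Pnliprp2 at 13.43 (11.34 to 11.77) and Fcgbp at 8.48 (10.01 to 10.47), and WT tumour 13 had Pyy at 9.58 (6.81 to 7.27). Among 4241 probe sets above the level filter without a single gene name, 156 were higher and 119 lower in KO.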

How the results depend on the processing

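All alternative settings reported here were planned tests, except the range covariate for the targeted probe sets, which was chosen after the result was seen. Over mouse means 195 genes were higher and 193 lower, within numbers 191 to 229 the counts were 12 and 18, with the 3′ to 5′ covariate 331 and 217, and at 2-fold or more 252 and 217. The filter at the 60th percentile gave 219 lower genes, with fewer genes tested (9187). With 1 tumour or mouse left out the counts ranged from 135 to 539 higher and from 153 to 406 lower, the lowest without mouse 72. For the other settings the cause was not tested. The stem cell list passed with the range covariate (−0.64). Its mean was −0.62 within 191 to 229, which holds 1 KO tumour, and ranged from −0.63 to −0.41 with samples left out. Fibroblast genes did not pass within 191 to 229 (−0.61), within 254 to 258 (−0.64), without a level filter (−0.45) or with the 3′ to 5′ covariate (−0.31), and ranged from −0.69 to −0.35. The mesenchymal list did not pass within 254 to 258 (−0.56) and ranged from −0.59 to −0.25. Glycolysis genes reversed their test direction within 254 to 258 (0.68). There WT tumour 1 was the lone WT tumour, with the lowest glycolysis mean of the WT tumours (10.02). The Wnt target, lymphocyte, MHC class II and interferon lists passed in every setting run with the preset correlation, except that the lymphocyte list could not be tested at the 60th percentile, with fewer than 5 members left. With an estimated correlation the adjusted p was 0.444 for Wnt targets, 0.781 for mesenchymal, 0.192 for lymphocyte, 0.781 for fibroblast, 0.255 for MHC class II and 0.444 for interferon genes. In fry, mesenchymal (0.315) and fibroblast genes (0.359) did not pass. For these lists the cause was not tested. Of 43 named genes past the threshold, 31 kept their call over mouse means, 13 within 191 to 229, 26 within 254 to 258 and 16 without mouse 72, and 0 changed sign in any setting.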

Other observations

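All 5 lists here were picked after the called genes were seen, so their tests were chosen after the result was seen, are not independent evidence of direction and leave open whether the lists move as groups.

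Genes of MHC class I processing, 13 tested, all rose in KO tumours. The immunoproteasome genes Psmb9 and Psmb8 were higher by 3.32 and 3.23 log2, the peptide transporter gene Tap1 6.01-fold and B2m 2.13-fold (cameraPR p = 7.32e-38, adjusted p = 0.0218 with an estimated correlation). Of 11 interferon-inducible GTPase genes, all rose, with Igtp at 11.1-fold and Irgm1 at 7.26-fold (p = 3.92e-30, adjusted p = 0.0300 with an estimated correlation). Of 9 plasma cell genes, 5 rose, Mzb1 by 6.51-fold and Pou2af1 by 6.42-fold, while Xbp1 had a difference of 0.05 log2 and did not pass (p = 6.76e-09, adjusted p = 0.0557 with an estimated correlation).

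Of 12 FGF and MAPK feedback genes, 4 fell (cameraPR p = 3.52e-07, adjusted p = 0.0653 with an estimated correlation). The growth factor gene Fgf3 fell 11.5-fold and the transcription factor gene Etv5 10.9-fold, beside Spred1 and Etv4 at −0.62 and −0.88 log2. Members that did not pass included Spry2, Dusp5 and Dusp6, at 0.18, 0.11 and −0.26 log2. Spry1, Spry4 and Dusp4, at −0.74, −0.79 and −0.73 log2, did not pass either. Of 12 Wnt ligands and secreted Wnt inhibitors, 6 fell, with Wnt6 at 13.8-fold, Dkk3 at 4.69-fold and Wnt5b at 3.42-fold lower levels, beside Dkk2, Wif1 and Notum of the Wnt target list. Wnt5a and Sfrp1 had differences of −0.42 and 0.04 log2 and did not pass (p = 8.35e-09, adjusted p = 0.0218 with an estimated correlation). The KO means of Fgf3 and Wnt6 and the WT means of Mzb1 and Pou2af1 lay under the level filter, so their folds are not exact.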
